A study of Mus musculus with 21 samples.

How the data were processed

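Epididymal white adipose tissue, the visceral fat depot attached to the epididymis, was taken from male C57BL/6j mice that were either conventionally raised, carrying a gut microbiota, or germ-free, kept without microbes. The mice ate ad libitum and tissue was taken every 4 hours, at zeitgeber times (ZT) 2, 6, 10, 14, 18 and 22 h after lights on. The series gave 12 conventional libraries, 2 at each time, and 9 germ-free libraries, 2 at ZT06, ZT10 and ZT22 and 1 at ZT02, ZT14 and ZT18. Libraries are named by group and by the replicate number in their titles. The labels do not say whether each library came from a separate mouse, so p-values measure the spread between these libraries.

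Per the labels' protocols, tissue was disrupted with a bead mill, RNA was purified with a column kit, and stranded total RNA libraries were made after removal of ribosomal RNA and sequenced as paired ends on an Illumina instrument. STAR 2.4.0i and genome build mm10 are named in the submitters' processing notes. The program that counted reads, its strand and multi-mapping settings and the annotation release are not given in the sources used here. The authors deposited 1 table of raw read counts over exons for 38087 genes, with an exon length per gene, and these counts were used as deposited. No mitochondrially encoded gene was present in the table, so no mitochondrial share was computed.

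Total counts per library ranged from 24388294 to 48348181. At these depths, small differences in genes at or below 1 CPM, a count scaled to a common library size, were not detectable. Gene symbols are those in the table. Positions and gene types came from the GENCODE M21 annotation of GRCm38, matched by gene identifier for 36308 of the 38087 genes. Reads of near-identical genes cannot be assigned with certainty without the counting settings, and values of such genes, among them the Serpina3 family, H2-Q10 and histone genes, are uncertain.

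Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and plots were drawn with Python 3.11.15 and matplotlib 3.10.9. Genes were kept with filterByExpr, which left 18334, and library sizes were scaled by the trimmed mean of M values (TMM). Levels were compared between the arms with edgeR's quasi-likelihood F test in 1 fit of all 21 libraries, with time as a 6-level factor. Rhythms were tested in a second fit with a mean, a cosine and a sine of period 24 h for each arm, over 2 degrees of freedom per arm. The difference of the rhythms was tested by the arm-by-cosine and arm-by-sine terms. P-values were adjusted by the Benjamini-Hochberg method and the threshold was an adjusted p of 0.05. CPM values are TMM-scaled, fold changes are on the log2 scale with their standard error (SE), and levels are means ± SD. An amplitude is the height of the fitted curve above its mean on the log2 scale.

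Gene lists for metabolic pathways, stress responses, immune and stromal cells, and the tissues next to the depot were fixed before the data were examined, and 30 of them were compared between arms with camera in limma at a preset correlation of 0.01. The same lists were tested with a correlation estimated per list and with fry. An exact permutation test of each list's mean log2 CPM, over all 5832 relabellings of the arms within time points, was chosen after seeing the data. For 12 clock genes, a common phase difference and amplitude ratio between the arms were computed from cosinor fits of log2 CPM with a prior count of 2, and tested 2-sided by exact permutation over the same 5832 relabellings. Markers of ciliated duct cells, liver, spermatids and male accessory glands were added after seeing the data and summed per library.

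The genes named were set by a rule fixed before the data were examined. For the arms, these were the 12 highest and the 12 lowest log2 fold changes among genes past the threshold with a mean log2 CPM of at least 1. Each list gave up to 4 members with the smallest p among those past the threshold, and up to 2 that did not pass. For rhythms, they were the core clock genes, the 10 genes with the smallest p in each arm, up to 3 list members rhythmic in conventional mice, and the 5 genes with the smallest p for the difference where none passed. Placeholder gene models and pseudogenes were skipped, and any other gene named is said to be chosen after its values were seen.

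The tests were checked on simulated counts drawn from the real means and library sizes, with 200 of 18334 genes changed between the arms. The changed genes were taken from those with a mean log2 CPM above 1, and counts were drawn independently for each gene. The rates below therefore do not cover genes at lower levels, correlation between genes or RNA of other tissues. The comparison of arms recovered 82% of genes changed 1.5-fold and 94% of those changed 2-fold, with 6 false calls among 190. For simulated log2 amplitudes of 0.5 and 1, the rhythm test recovered 66.7% and 90.7% of genes in conventional mice and 56% and 86.7% in germ-free mice. The test of differing rhythms recovered 26% and 86% at these amplitudes. Alternatives covered the size factors, the filter, the test, a replicate block, the threshold, the time term, the most abundant genes, the prior count and each library left out in turn. Others, chosen after seeing the data, left out libraries high in ciliated duct markers, used that marker score as a covariate, removed each library's trend with exon length and GC content, or took each replicate number alone.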

Results

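Total RNA of epididymal white fat was profiled in 12 libraries of conventionally raised and 9 libraries of germ-free male mice, sampled every 4 h over 1 day. The design addressed how the fat of mice without a microbiota differs from that of mice with one, and whether its daily rhythms differ. Total counts per library did not pass between the arms after adjustment over 16 library measures (2-sided exact permutation p = 0.00980, adjusted p = 0.0784). For each library, the deviation of each gene's log2 CPM from its mean over all libraries was correlated with exon length across genes. Such a trend can reflect RNA integrity or fragmentation. Expression differences between long and short genes can give it too, and its source was not tested. The trend averaged rho 0.131 ± 0.0963 in conventional and -0.146 ± 0.168 in germ-free libraries (exact permutation p = 0.000279, adjusted p = 0.00446). Because the deviations are centred over the libraries, the signs are relative between libraries. Genes are not independent replicates, so these rho values describe libraries only.

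Transcripts of neighbouring tissues appeared in some libraries of both arms. Summed markers of ciliated duct cells ranged from 0.328 to 681 CPM, with medians of 43.6 in conventional and 5.17 in germ-free mice. They exceeded 5 times the median of all libraries, 11.0 CPM, in 8 libraries: the conventional ones at ZT02 (replicates 1 and 2) and replicate 2 at ZT06, ZT14, ZT18 and ZT22, and the germ-free ones at ZT22 (replicate 1) and ZT06 (replicate 2). Male accessory gland markers reached 1563 CPM in the conventional library at ZT10, replicate 2, where epididymis and testis markers stood at 872 CPM. Liver markers had a median of 130 CPM in libraries numbered 1 and 45.4 CPM in those numbered 2, with a log2 difference of means of 1.06 (exact permutation p = 0.0661). All libraries numbered 1 lay between 113 and 299 CPM. Those numbered 2 lay between 30.7 and 58.7 CPM, except the conventional library at ZT02, the highest at 879 CPM, and the germ-free one at ZT14, at 523 CPM. Apart from these, the libraries of the 2 numbers did not overlap. Liver markers averaged 159 CPM in conventional and 145 CPM in germ-free libraries (exact permutation p = 0.906).

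**Figure D1:**
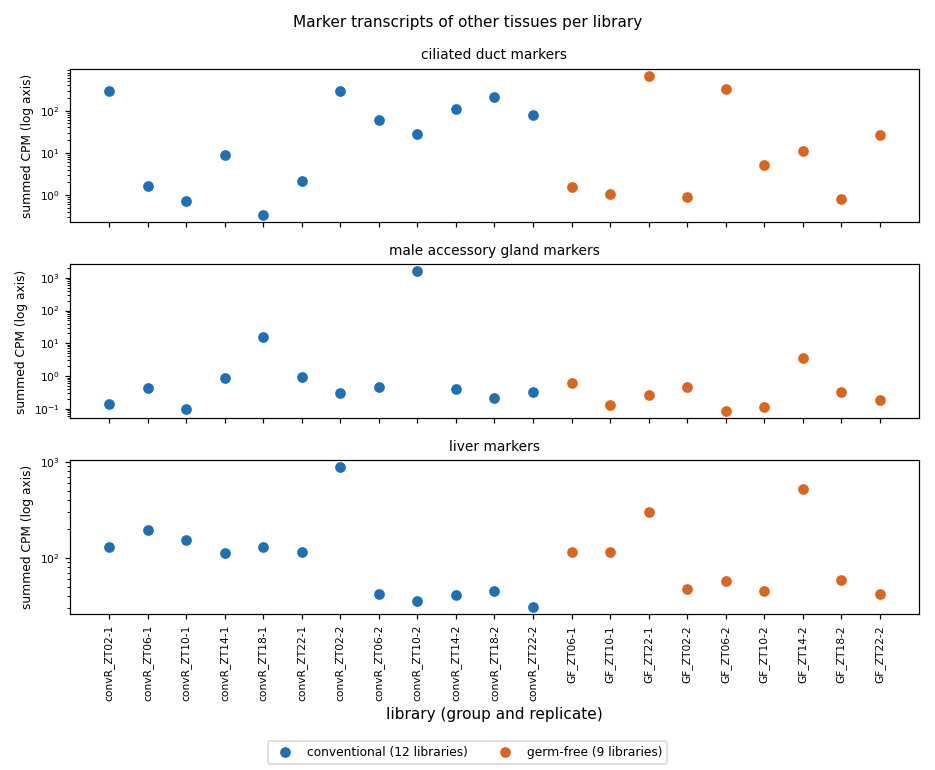
Summed CPM, on log axes, of markers of ciliated duct cells, male accessory glands and liver in each of the 21 libraries, named by group and replicate number; each point is a library. Ciliated duct markers ranged from 0.328 to 681 CPM and male accessory gland markers reached 1563 CPM in 1 conventional library.

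Among the genes that differed between germ-free and conventional fat were lipid enzymes, which were higher, and chains of type I collagen, which were lower. Elovl6, which lengthens saturated fatty acids, stood at 71.4 ± 66.6 CPM (SD, n = 12) in conventional and 374 ± 463 CPM (SD, n = 9) in germ-free mice, a log2 fold change of 2.19 ± 0.58 (SE, adjusted p = 0.0115). Without the germ-free library at ZT22, replicate 2, the germ-free mean of Elovl6 was 226 ± 132 CPM. Acsl1, which activates long-chain fatty acids, rose from 1423 ± 446 to 3223 ± 1165 CPM (log2 fold change 1.14 ± 0.11, adjusted p = 2.79e-05). Col1a1, a chain of type I collagen, fell from 299.8 ± 44.0 to 122 ± 39.9 CPM (log2 fold change -1.33 ± 0.16, adjusted p = 1.07e-04), and every germ-free library lay below every conventional one. In all, 4909 of 18334 genes differed between the arms, of which 2794 were higher and 2115 lower in germ-free mice. At the times with 2 libraries in each arm alone, 525 were higher and 1163 lower. Changes over 2-fold were found for 84 higher and 114 lower genes, and for 122 genes the arms did not overlap, where chance separates a share of 6.80e-06.

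The genes with the highest fold changes included Acly and Gys2, and Cidea and Cox8b of thermogenic fat. Acly and Acss2, which supply acetyl-CoA for lipid synthesis, had log2 fold changes of 1.71 ± 0.50 (adjusted p = 0.0193) and 1.49 ± 0.39 (adjusted p = 0.0114). Gys2, a glycogen synthase, rose from 6.70 ± 4.06 to 26.4 ± 18.1 CPM, and Ppp1r3b, a regulator of glycogen synthesis, from 16.2 ± 11.5 to 54.2 ± 58.7 CPM (adjusted p = 0.0480). Cidea, a lipid droplet protein, and Cox8b, a cytochrome oxidase subunit of thermogenic fat, rose by 1.78 ± 0.39 and 1.69 ± 0.30 on the log2 scale. Lrtm1 (1.69 ± 0.21), Cyp2f2 (1.46 ± 0.23) and the plasma protein gene Itih4 (1.45 ± 0.29) rose as well. Serpina3j (2.58 ± 0.51) and H2-Q10 (1.94 ± 0.41) complete the 12 highest, but belong to families of near-identical genes, and their values are uncertain.

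Among the lowest were Prkag3, a regulatory subunit of the energy sensor AMPK, at 4.95 ± 1.67 CPM in conventional and 0.938 ± 0.464 CPM in germ-free mice (log2 fold change -2.37 ± 0.29, adjusted p = 1.20e-04), and Oxtr, the oxytocin receptor, at 70.3 ± 27.9 and 17.7 ± 11.8 CPM (-2.09 ± 0.35, adjusted p = 8.20e-04). The calcium channel gene Cacna1e (-1.94 ± 0.38), the transcription factor gene Klf14 (-1.79 ± 0.35), Rab15 (-1.71 ± 0.24) and Atp6v0d2, a proton pump subunit (-1.46 ± 0.42), were lower too. So were Zyg11a (-1.34 ± 0.24), Creb3l1 (-1.32 ± 0.15), a transcription factor gene linked to collagen production, Vgll3 (-1.29 ± 0.24) and Sez6l (-1.28 ± 0.22). In M21 annotation of GRCm38, Elovl6 lies on chromosome 3 at 129532355 to 129638495 and Col1a1 on chromosome 11 at 94936224 to 94953042. The call for Acly was lost without the germ-free library at ZT18, replicate 2 (adjusted p = 0.0631), and that for Ppp1r3b without any of 16 single libraries (adjusted p up to 0.188). Libraries numbered 2 gave 957 genes, 900 of them shared with the fit of all libraries, which holds these same libraries. Those numbered 1, with 3 germ-free libraries, gave 0 by edgeR with 2544 at an unadjusted p under 0.05, and no other tool was run on these. With time as a 6-level factor, that fit had few residual degrees of freedom, so its 0 does not show that the arms are alike. Between the separate fits of the 2 numbers, log2 fold changes correlated with r = -0.0386 and rho = 0.440 over 17982 genes.

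**Figure D2:**
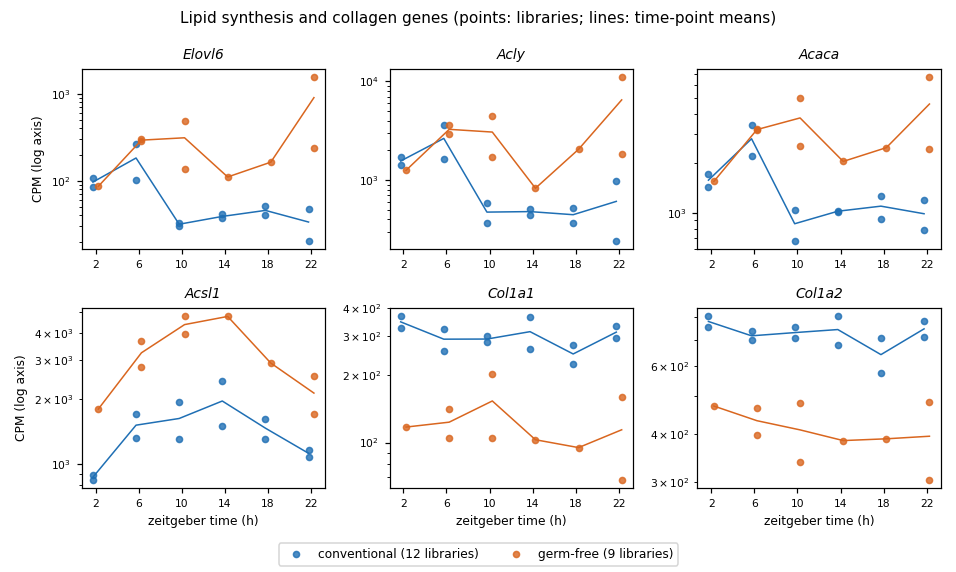
CPM on log axes against zeitgeber time (h) for 4 lipid genes and 2 collagen genes; points are libraries and lines join the means of each time point, for 12 conventional and 9 germ-free libraries. Col1a1 ranged from 224 to 369 CPM in conventional and from 68.1 to 202 CPM in germ-free libraries, and Elovl6 reached 1565 CPM in a germ-free library and 262 CPM in a conventional one.

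Lists of lipid synthesis were higher in germ-free mice with camera's preset correlation. None passed with an estimated correlation, where the adjusted p was 0.734 for de novo lipogenesis, 0.536 for triglyceride synthesis and lipid uptake and 0.711 for cholesterol synthesis. In de novo lipogenesis, the making of fatty acids from acetyl-CoA, 9 of 19 members rose, 0 fell and 10 did not pass, with Elovl6, Acss2, Acaca (1.22 ± 0.29, adjusted p = 0.00622) and the citrate carrier gene Slc25a1 (1.07 ± 0.29, adjusted p = 0.0130) leading. Adjusted over the list alone, 10 members rose, and the list had an adjusted p of 3.00e-04 with camera and of 0.0753 with fry. Fasn, fatty acid synthase, chosen after its values were seen, had a log2 fold change of 1.17 ± 0.40 (adjusted p = 0.0391), a call lost without any of 12 single libraries (adjusted p up to 0.0844). In triglyceride synthesis and lipid uptake, 8 of 22 members rose, 1 fell and 13 did not pass, and 9 rose and 1 fell adjusted over the list alone. The list had a camera adjusted p of 9.33e-05. Besides Acsl1, its members Dgat1, which makes triglycerides (0.74 ± 0.10), and the fatty acid binding protein gene Fabp5 (0.91 ± 0.15) rose, and the member that fell was the lipoprotein receptor gene Vldlr (-0.22 ± 0.06, chosen after its values were seen). In cholesterol synthesis, 8 of 21 members rose, 0 fell and 13 did not pass, while 12 rose and 1 fell adjusted over the list alone. Insig1, an inhibitor of sterol synthesis (1.15 ± 0.30), and Fdps (0.92 ± 0.25) were among them. The camera adjusted p was 1.01e-04. Without the germ-free library at ZT18, replicate 2, 5 de novo lipogenesis and 4 cholesterol synthesis genes rose, and 5 of the latter without the conventional library at ZT22, replicate 1, or the germ-free one at ZT10, replicate 1. At the times with 2 libraries in each arm alone, 1 de novo lipogenesis, 4 triglyceride synthesis and 1 cholesterol synthesis genes rose. In that smaller set of libraries the list medians were 0.67, 0.29 and 0.56 on the log2 scale, against 0.52, 0.30 and 0.47 over all libraries. Their camera adjusted p with the preset correlation was 3.46e-06, 0.00482 and 1.10e-06, in the same order.

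Mitochondrial lists were higher too with camera. None passed with an estimated correlation, where the adjusted p was 0.510 for oxidative phosphorylation and 0.540 for both fatty acid oxidation and thermogenic adipocyte genes. All 25 oxidative phosphorylation genes, all encoded in the nucleus, were higher in germ-free mice, with a median log2 fold change of 0.44, and 25 passed adjusted over the list alone. Examples were Ndufv1 of complex I (0.49 ± 0.07, adjusted p = 1.78e-04) and Cox4i1 of complex IV (0.47 ± 0.07, adjusted p = 4.80e-04). The list's camera adjusted p was 1.12e-22. Of 19 fatty acid oxidation genes, 13 rose, 2 fell and 4 did not pass, and 14 rose and 2 fell adjusted over the list alone. Hadh (0.40 ± 0.07) and Acadvl (0.44 ± 0.08), enzymes of beta-oxidation, rose. Among the members that fell was Cpt1a (-0.25 ± 0.08, chosen after its values were seen), a call lost without any of 9 single libraries (adjusted p up to 0.0989). The list had a camera adjusted p of 1.01e-04. Of 12 thermogenic adipocyte genes, 4 rose, 0 fell and 8 did not pass, with 4 rising adjusted over the list alone. They were Cidea, Cox8b, Dio2 (1.66 ± 0.33), which activates thyroid hormone, and Ppargc1a, a coactivator of mitochondrial genes (0.52 ± 0.16), whose call was lost without any of 8 single libraries (adjusted p up to 0.100). This list's camera adjusted p of 0.0452 was 0.0513 with the ciliated duct score as a covariate, an alternative chosen after seeing the data, and the call was lost without the conventional libraries at ZT10, replicate 1 (0.0584), ZT10, replicate 2 (0.0620), and ZT22, replicate 2 (0.0529), or the germ-free ones at ZT22, replicate 1 (0.0515), and ZT10, replicate 2 (0.0528). Without the germ-free library at ZT14, replicate 2, 8 fatty acid oxidation genes rose. At the times with 2 libraries in each arm alone, 8 oxidative phosphorylation genes rose, 1 fatty acid oxidation gene rose and 1 fell, and 2 thermogenic genes rose. In that smaller set of libraries the list medians were 0.39, 0.28 and 0.70 on the log2 scale, against 0.44, 0.31 and 0.49 over all libraries. Their camera adjusted p with the preset correlation was 2.19e-14, 0.0378 and 0.00217, in the same order. Across genes, fold changes fell with exon length (rho = -0.308 over 13804 genes).

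Extracellular matrix, immediate early, cell cycle and macrophage lists were lower in germ-free fat with camera's preset correlation. None passed with an estimated correlation, where the adjusted p was 0.404, 0.536, 0.711 and 0.734 in that order. Of 27 extracellular matrix genes, 17 fell, 1 rose and 9 did not pass, and 19 fell and 1 rose adjusted over the list alone. Besides Col1a1, the fibrillar collagen genes Col1a2 (-0.82 ± 0.09, adjusted p = 4.51e-05) and Col5a1 (-0.82 ± 0.08, adjusted p = 3.36e-05) and the microfibrillar Col6a3 (-0.63 ± 0.08) fell without overlap of the arms. The member that rose was the protease gene Mmp3 (0.73 ± 0.25, chosen after its values were seen), a call lost without any of 13 single libraries (adjusted p up to 0.129). The list had a camera adjusted p of 1.31e-15, while for adipose progenitor and fibroblast markers 1 of 17 fell and the camera adjusted p was 0.551. At the times with 2 libraries in each arm alone, 19 matrix genes and 2 progenitor and fibroblast markers fell, and the latter list passed (camera adjusted p = 0.0286). Of 22 immediate early genes, which respond within minutes to stimuli and to tissue handling, 6 fell and 16 did not pass, and 7 fell adjusted over the list alone. Fos (-1.06 ± 0.21), Egr1 (-0.94 ± 0.18) and Zfp36 (-0.63 ± 0.13) fell, with a camera adjusted p of 5.75e-05.

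Of 24 cell cycle genes, 7 fell and 17 did not pass, and 10 fell adjusted over the list alone. Mki67, a marker of cycling cells (-0.69 ± 0.13), and Top2a (-0.51 ± 0.13) fell, and the list's camera adjusted p of 0.00167 was 0.711 with an estimated correlation. Without the 8 libraries high in ciliated duct markers, a set chosen after seeing the data, the camera adjusted p of this list was 0.0639. In the cell cycle list 11 genes fell without the germ-free library at ZT22, replicate 1, and 1 at the times with 2 libraries in each arm alone. At those times the list median was -0.28 on the log2 scale, against -0.32 over all libraries (camera adjusted p = 0.0281 with the preset correlation). Of 23 macrophage genes, 5 fell and 18 did not pass, and 5 fell adjusted over the list alone. Without the germ-free library at ZT02, replicate 2, 11 macrophage genes fell, and 3 without that at ZT14, replicate 2. The integrin genes Itgax (-0.52 ± 0.15) and Itgam (-0.43 ± 0.13) fell, and the list's camera adjusted p of 0.00418 was 0.734 with an estimated correlation, 0.122 with fry and 0.0799 by the exact permutation test. Its summed markers stood at 1905 ± 242 CPM in conventional and 1648 ± 395 CPM in germ-free libraries (exact permutation p = 0.0804).

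**Figure D3:**
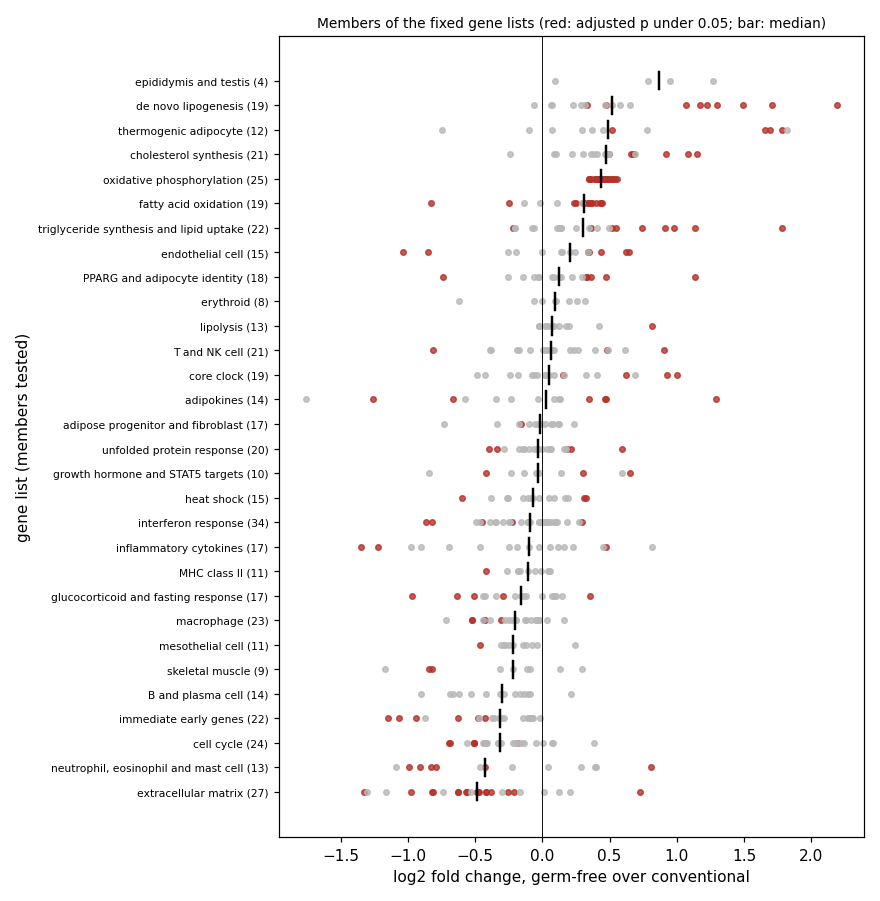
Log2 fold changes, germ-free over conventional, of the tested members of each fixed gene list, with the number tested in brackets; red points passed an adjusted p of 0.05 and bars mark list medians. All 25 oxidative phosphorylation genes lay above 0, with a median of 0.44, and the median of the 27 extracellular matrix genes was -0.49.

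The other lists did not pass with camera in the main fit. With length and GC offsets, an alternative chosen after seeing the data, 3 of them passed. They were the endothelial cell (adjusted p = 0.0330), mesothelial cell (0.0255) and glucocorticoid and fasting response (0.0416) lists. Without the 8 libraries high in ciliated duct markers, the mesothelial cell list passed (0.00358). Endothelial markers moved both ways, with 5 of 15 higher and 2 lower (adjusted p = 0.132): Kdr, a receptor for vascular endothelial growth factor, rose (0.65 ± 0.09, adjusted p = 2.32e-04) and Vwf, von Willebrand factor, fell (-1.03 ± 0.18, adjusted p = 0.00105). Markers of neutrophils, eosinophils and mast cells had 1 of 13 higher and 5 lower (adjusted p = 0.132), among them the mast cell genes Kit (0.81 ± 0.18) and Cpa3 (-0.99 ± 0.25). Adipocyte identity genes had 5 of 18 higher and 1 lower (adjusted p = 0.0729), with Retn, resistin, higher (0.47 ± 0.12) and Aoc3 lower (-0.74 ± 0.12). Adipokines had 4 of 14 higher and 2 lower (adjusted p = 0.802), with a median log2 fold change of 0.02 and a mean of -0.14. Apln, apelin, rose from 8.37 ± 2.04 to 20.1 ± 10.1 CPM (1.29 ± 0.20, adjusted p = 4.84e-04), and Lep, leptin, chosen after its values were seen, fell from 1142 ± 327 to 685 ± 292 CPM (-0.67 ± 0.18, adjusted p = 0.0123). The glucocorticoid and fasting list had 1 of 17 higher and 4 lower (adjusted p = 0.0649), with Mt2, a metallothionein gene (-0.97 ± 0.21), and Foxo1 (-0.51 ± 0.12) lower. Lipolysis genes had 1 of 13 higher (adjusted p = 0.103), Adora1, an adenosine receptor gene (0.82 ± 0.09). Core clock genes had 4 of 19 higher and 0 lower in mean level (adjusted p = 0.528), among them Cry1 (0.62 ± 0.13).

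Immune and stress lists also did not pass. Interferon genes had 1 of 34 higher and 4 lower (adjusted p = 0.130), with Oas2 lower (-0.82 ± 0.17), inflammatory cytokine genes 1 of 17 higher and 2 lower (adjusted p = 0.341), with Saa3 lower (-1.22 ± 0.28), and class II antigen presentation genes 1 of 11 lower (adjusted p = 0.340), their regulator Ciita (-0.42 ± 0.12). T and natural killer cell genes had 2 of 21 higher and 1 lower (adjusted p = 0.786), with Klrb1c higher (0.90 ± 0.20) and Il7r lower (-0.81 ± 0.19). B and plasma cell genes had 0 of 14 higher or lower (adjusted p = 0.241), and erythroid genes 0 of 8 (adjusted p = 0.786). The unfolded protein response list had 3 of 20 higher and 2 lower (adjusted p = 0.786), with Asns higher (0.59 ± 0.08), and heat shock genes 2 of 15 higher and 1 lower (adjusted p = 0.790), with Cirbp higher (0.33 ± 0.07) and Bag3 lower (-0.60 ± 0.10). Growth hormone targets had 2 of 10 higher and 1 lower (adjusted p = 0.892, direction up, with a median log2 fold change of -0.04), with Igfbp3 higher (0.65 ± 0.09) and Igf1 lower (-0.42 ± 0.10). Among other tissues, 1 of 11 mesothelial genes was lower (Wt1, -0.46 ± 0.07, list adjusted p = 0.0579), 2 of 9 skeletal muscle genes were lower (Actn3, -0.82 ± 0.20, and Myh2, -0.84 ± 0.24, list adjusted p = 0.132) and 0 of 4 epididymis and testis genes passed (list adjusted p = 0.802).

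Leaving out 1 library moved the counts and brought some of these lists past the threshold. With single libraries left out, 3 to 9 endothelial and 2 to 6 adipocyte identity genes were higher. Lower were 1 to 6 genes in each of the interferon, mesothelial, and neutrophil, eosinophil and mast cell lists. Without the 8 libraries high in ciliated duct markers, 0 neutrophil, eosinophil and mast cell genes were lower. The mesothelial cell list passed without any of 8 libraries, with its lowest adjusted p, 0.00141, without the germ-free library at ZT02, replicate 2. Without the germ-free library at ZT22, replicate 1, the PPARG and adipocyte identity (0.00551), endothelial cell (0.0261), lipolysis (0.0223) and mesothelial cell (0.0295) lists passed. Without that at ZT18, replicate 2, the endothelial cell (0.0402), B and plasma cell (0.0483) and neutrophil, eosinophil and mast cell (0.0342) lists did. The glucocorticoid and fasting response list passed without the germ-free library at ZT14, replicate 2 (0.00431), or the conventional ones at ZT14, replicate 1 (0.0377), ZT14, replicate 2 (0.0429), and ZT02, replicate 2 (0.0269). The interferon response list passed without the germ-free library at ZT22, replicate 2 (0.0169), or the conventional one at ZT02, replicate 1 (0.0433). In conventional mice, ZT06, replicate 1, decided the erythroid (0.0377) list, ZT18, replicate 1, the endothelial cell list (0.0118), ZT22, replicate 2, the lipolysis list (0.0354), and ZT06, replicate 1 (0.0498), ZT22, replicate 1 (0.0191), and ZT22, replicate 2 (0.0409), the PPARG and adipocyte identity list.

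With camera, 10 of 30 lists passed, and with an estimated correlation 0, where 2 had an unadjusted p under 0.05. With fry, 9 passed, 8 of them among the 10: de novo lipogenesis (adjusted p = 0.0753) and macrophage (0.122) did not, and skeletal muscle (0.00571) did. By the exact permutation test of list means, chosen after seeing the data, 12 lists passed. They were 9 of the 10, all but the macrophage list (adjusted p = 0.0799), and also the skeletal muscle (0.0304), glucocorticoid and fasting (0.0304) and adipokine (0.0369) lists, all 3 lower in germ-free mice. For oxidative phosphorylation and for triglyceride synthesis, the exact p of 0.000171 (adjusted p = 0.00257) was the smallest the relabellings can give.

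The molecular clock ran in both arms. Dbp, a clock output gene, peaked at ZT10.1 with a log2 amplitude of 1.71 ± 0.19 (SE) in conventional mice and at ZT9.84 with 2.36 ± 0.22 in germ-free mice (adjusted p = 6.42e-04 and 4.98e-05). Arntl, the clock activator Bmal1, peaked near the end of the night, at ZT23.1 with an amplitude of 1.65 ± 0.25 and at ZT22.4 with 2.49 ± 0.20. In conventional mice 146 genes were rhythmic, of which 114 peaked in the dark phase and 32 in the light phase, with 2554 at an unadjusted p under 0.05. In germ-free mice 828 were, 445 with peaks in the dark and 383 in the light, with 4099 at an unadjusted p under 0.05. The arms shared 92 rhythmic genes, where independent lists would share 6.59, and in these the germ-free peak came earlier by a median of -0.94 h, quartiles -1.66 and -0.378 h, a shift that was not tested. The counts changed with the method: they were 815 and 2044 with DESeq2 and 252 and 522 with time as a 6-level factor, and conventional libraries matched in number to the germ-free ones gave 9.

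Of 19 core clock genes, 14 were rhythmic in conventional mice, 15 in germ-free mice and 14 in both, with 18 and 17 adjusted over the list alone. The Period genes Per3 and Per2 peaked at ZT12.0 and ZT14.6 in conventional and at ZT11.6 and ZT13.4 in germ-free mice, and Cry1, a repressor, at ZT17.2 and ZT18.4. Nr1d1, the repressor Rev-erb alpha, had amplitudes of 1.62 ± 0.30 and 2.26 ± 0.21, and Npas2 of 1.14 ± 0.22 and 1.99 ± 0.15. Tef, Hlf and Nr1d2 were rhythmic in both arms, and Ciart, listed under its older name Gm129, was as well. Nfil3 passed in germ-free mice alone, where its amplitude was 1.88 ± 0.24 against 0.81 ± 0.30 (difference adjusted p = 0.654), and Cry2, Bhlhe40 and Bhlhe41 passed in neither arm. Single libraries decided some calls in conventional mice: Clock was lost without ZT14, replicate 1 (adjusted p = 0.0528), Nr1d1 without ZT10, replicate 1 (0.0541), ZT06, replicate 2 (0.0503), or ZT18, replicate 2 (0.0558), and Ciart, Npas2, Rora and Per1 without any of 4, 5, 5 and 11 libraries (adjusted p up to 0.0942, 0.114, 0.114 and 0.114). In germ-free mice, Per2 was lost without ZT14, replicate 2 (0.0670).

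**Figure D4:**
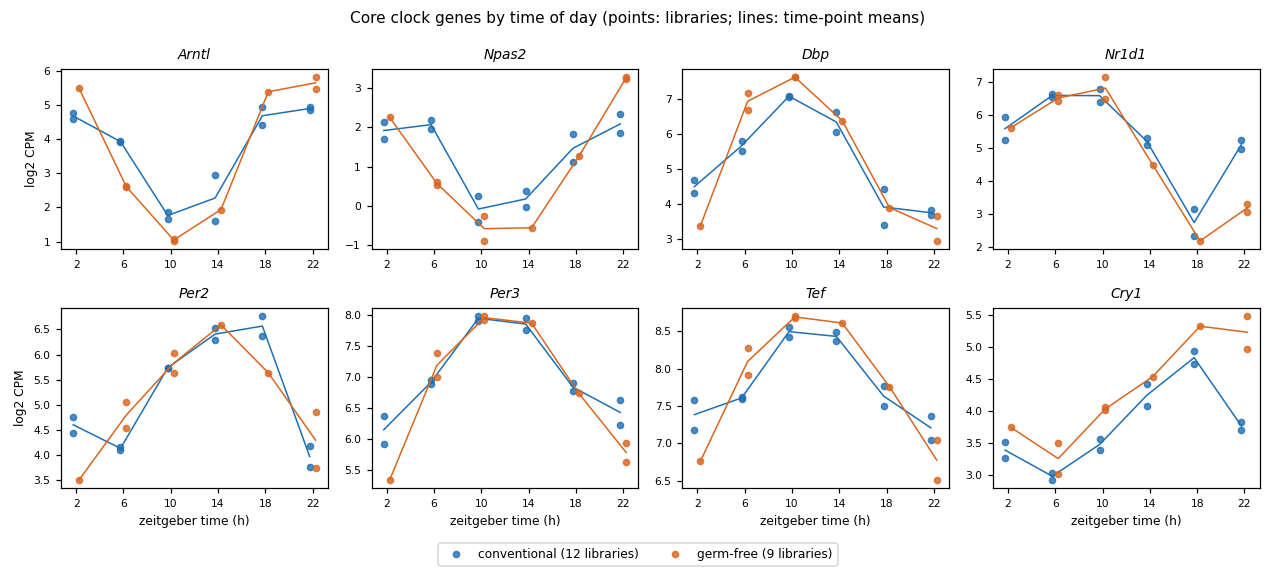
Log2 CPM against zeitgeber time (h) for 8 core clock genes; points are libraries and lines join the means of each time point, for 12 conventional and 9 germ-free libraries. The curves of Dbp peak near ZT10 in both arms, with fitted log2 amplitudes of 1.71 in conventional and 2.36 in germ-free mice.

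Among the other genes with the smallest p, the transcription factor gene Camta1 peaked at ZT12.0 and ZT11.5, the tetraspanin gene Tspan4 at ZT14.8 and ZT13.7, and the chromatin remodelling gene Smarca2 at ZT14.9 and ZT14.3, in conventional and germ-free mice. Acsm5, a fatty acid activating enzyme, and Crtac1 had amplitudes of 0.74 ± 0.07 and 1.92 ± 0.26 in conventional mice, and 0.69 ± 0.14 and 1.42 ± 0.17 in germ-free mice. In germ-free mice, Dtx4 (1.44 ± 0.15), Osgin1 (1.55 ± 0.09) and N4bp2l1 (0.64 ± 0.05) were also among the 10 with the smallest p, and were rhythmic in conventional mice too. List members with a rhythm in conventional mice included the adipokine gene Nrg4 (0.75 ± 0.10), the matrix protease gene Mmp2 (0.35 ± 0.08), the glucocorticoid target Tsc22d3 (0.72 ± 0.13) and Asns (0.36 ± 0.07).

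The count in conventional mice, 146, was 96 without the library at ZT02, replicate 1, 84 without ZT10, replicate 1, 50 without ZT14, replicate 1, 93 without ZT22, replicate 1, 82 without ZT06, replicate 2, 81 without ZT10, replicate 2, and 247 without the germ-free library at ZT02, replicate 2. The count in germ-free mice, 828, was 370 without ZT10, replicate 2, and 504 without ZT14, replicate 2. Without the 8 libraries high in ciliated duct markers the counts were 8 and 410. That omission took out more conventional than germ-free libraries and left no conventional one at ZT02, so the fall cannot be laid to duct RNA alone. Libraries numbered 2 alone gave 0 in conventional mice by edgeR, with 626 at an unadjusted p under 0.05, and 85 in germ-free mice.

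Clock genes had larger amplitudes in germ-free fat, and no common difference in phase was detected. Over 12 clock genes the summed amplitude was 1.51 times that of conventional mice (2-sided exact permutation p = 0.00137, smallest possible 0.000171), and 12 of 12 had a larger amplitude in germ-free mice. The 12, fixed in advance, were Arntl, Npas2, Per2, Per3, Cry1, Nr1d1, Nr1d2, Dbp, Tef, Ciart, Nfil3 and Bhlhe41. Over all core clock genes the ratio was 1.46 (exact permutation p = 0.00120), and Cry2 (0.719) and Bhlhe40 (0.722) had smaller fitted amplitudes in germ-free mice. Their rhythms passed in neither arm when adjusted over all genes. Adjusted over the list alone, both passed in conventional mice by the rhythm test (adjusted p = 0.00568 and 0.0292). The mean log2 amplitude was 1.15 ± 0.38 in conventional and 1.73 ± 0.59 in germ-free mice (SD over the 12 genes). The common phase difference was -0.37 h (exact permutation p = 0.547), and relabelled arms gave -1.22 to 1.35 h in their central 95%. A shift within this range could not be told from none. Without the 8 libraries high in ciliated duct markers, which include every conventional one at ZT02, the amplitude ratio was 1.29 (exact permutation p = 0.0521). With libraries numbered 2 alone it was 1.68 (exact permutation p = 0.0313).

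No single gene passed the test of differing rhythms: edgeR gave 0 genes, with 1392 (7.59%) at an unadjusted p under 0.05, limma-voom 0 and DESeq2 48. The smallest p belonged to Pak3, a kinase gene with a log2 amplitude of 0.11 ± 0.06 in conventional and 0.66 ± 0.05 in germ-free mice (difference adjusted p = 0.188). Serpina3m (0.232), whose values are uncertain as those of a family of near-identical genes, Ptpn4 (0.232), Serpina3k (0.281), of the same family, and the choline dehydrogenase gene Chdh (0.336) followed. Chdh peaked at ZT19.9 in conventional and at ZT14.9 in germ-free mice, with amplitudes of 0.49 ± 0.06 and 0.51 ± 0.11, the latter call being lost without the library at ZT14, replicate 2 (adjusted p = 0.0610). Without the germ-free library at ZT18, replicate 2, 3 genes passed.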

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

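The tests of explanations in this part were all chosen only after the results they concern were seen, while the comparison of clock amplitudes was planned. Of 16 library measures examined among the 9 germ-free libraries, 5 had 1 library far from the others, and chance flags about 1 in 20 groups when values are normal, a rate not measured for these skewed sums of markers. The germ-free library at ZT22, replicate 1, had the lowest share of its counts in tested genes, 99.76%, where the next lowest had 99.87%. The same library held 681 CPM of ciliated duct markers, against 334 CPM in the next highest. Male accessory gland markers stood at 3.63 CPM in the germ-free library at ZT14, replicate 2, and at most at 0.617 CPM in the others. Skeletal muscle markers reached 84.6 CPM and B and plasma cell markers 981 CPM in the germ-free library at ZT02, replicate 2, against 26.6 and 319.6 CPM in the next highest germ-free library, while the conventional library at ZT02, replicate 2, held 97.0 and 1018 CPM. No biological explanation was tested for these libraries.

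The summed amplitude of 12 clock genes was 1.51 times as large in germ-free as in conventional mice, and this difference between the arms passed an exact permutation test (p = 0.00137). The unequal number of libraries is not the whole cause, since the ratio was 1.44 or more in each of the 8 choices of 9 conventional libraries matched to the germ-free ones by time. RNA of ciliated duct cells cannot be told apart from a difference between the arms, because the ratio without the 8 libraries high in their markers was 1.29 (exact permutation p = 0.0521) with only 96 relabellings left. Those 8 libraries include every conventional one at ZT02. More scatter in the timing of conventional mice also stays open, as 2 measures of spread went opposite ways. The residual spread about the fitted curves was 1.14 times that of germ-free mice, between the bounds set for either outcome. The SD between the 2 libraries of a time point was smaller in conventional mice, 0.306 against 0.357 on the log2 scale. The germ-free value rests on ZT06, ZT10 and ZT22 alone, and this difference was not tested. A stronger daily rhythm in mice without a microbiota may also underlie the ratio of 1.51, but the design cannot part it from the open explanations.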

How the results depend on the processing

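The alternatives on ciliated duct markers, exon length and GC content and single replicate numbers, and, for lists, the exact test, the 2-library times, the other time terms and omission of the 50 most abundant genes, were chosen only after the results were seen. Of the 4909 genes differing between arms, 2461 passed at an adjusted p under 0.01. Times with 2 libraries in each arm gave 1688 genes (1493 shared, 31.1% higher), omission of the libraries high in ciliated duct markers 3150 (2659 shared), libraries numbered 2 alone 957 and libraries numbered 1 alone 0 by edgeR (2544 at an unadjusted p under 0.05). Other alternatives gave 3842 to 5358, and single libraries left out 3328 to 5245. The share of higher genes, 56.9%, was 49.8% with CPM above 1 in at least 9 libraries and 50.7% with length and GC offsets. Rhythmic genes in conventional and germ-free mice, 146 and 828, were 94 and 545 with no filter on low counts (32101 genes tested), 815 and 2044 with DESeq2, 53 and 225 at an adjusted p under 0.01, 252 and 522 with time as a 6-level factor, 8 and 410 without libraries high in ciliated duct markers, and 0 and 85 with libraries numbered 2 alone. Conventional libraries matched in number gave 9. Single libraries left out gave 50 to 247 in conventional and 370 to 1065 in germ-free mice. Rhythms differing between arms numbered 0, 48 with DESeq2 and 0 to 3 with single libraries left out. Lists past the threshold, 10, were 19 at times with 2 libraries in each arm, 16 with libraries numbered 2 alone, 14 with those numbered 1 alone, 0 with an estimated correlation and 9 to 13 with single libraries left out. The clock amplitude ratio, 1.51, was 1.29 without libraries high in ciliated duct markers, and 1.43 to 1.61 with single libraries left out. With libraries numbered 1 alone, Mmp3 reversed from 0.73 to -0.0841 and Ahr from 0.18 to -0.0403. That fit had 3 germ-free libraries and few residual degrees of freedom. Part of the lower counts follows from fewer libraries, a stricter threshold or more genes tested, and the cause of the others was not tested. With the replicate number as a block, 4588 genes and 10 lists differed and 115 and 685 genes were rhythmic. Differences between replicates 1 and 2 correlated across genes between the arms with r of 0.503 at ZT06, 0.150 at ZT10 and -0.290 at ZT22, and between times in conventional mice with a median r of 0.374, so the numbers do not pair the arms but may mark a shared condition (957 genes with those numbered 2 alone). Over summary values, 200 comparisons with an alternative kept their side, 25 grew weaker and 8 stronger; rhythms with libraries numbered 1 alone were not run. At these depths, genes near 1 CPM limit what can be seen.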

Other observations

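The tests of explanations and the relabellings of the libraries in this part were chosen only after the results were seen. With the arms relabelled within time points, 1 of 60 splits, the real one, gave as many genes as the 4909 observed. The highest other gave 2587 and kept 8 of the 9 germ-free libraries together. Chance is unlikely for this count, but 60 splits cannot exclude it. For gene lists chance cannot be excluded as the source of the count, since 30 of 60 splits gave 10 or more lists and the highest other 18. For genes with a rhythm differing between arms, the real count by edgeR was 0 (limma-voom 0, DESeq2 48), so 60 of 60 splits reach it by construction and this count decides nothing (highest other 3). At an unadjusted p under 0.05, 13 of 60 splits had as many as the 1392 genes observed, so chance cannot be excluded there. With times relabelled within arms, 1 of 60 splits gave as many rhythmic genes as the 146 in conventional mice (highest other 4), and 1 of 60 as many as the 828 in germ-free mice (highest other 302). Chance is unlikely for both, but 60 splits cannot exclude it.

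Oxidative phosphorylation genes were higher and extracellular matrix genes lower in germ-free mice. Against exon length and GC bias as the whole cause, 25 oxidative phosphorylation genes and 15 matrix genes passed in the same direction after offsets for both. Without the 8 libraries high in ciliated duct markers, 25 and 19 passed, which speaks against RNA of these cells. A smaller share of stromal cells as the whole cause is argued against by the matrix list falling further than the progenitor and fibroblast list, by a log2 difference of -0.43 (exact permutation p = 0.000171, the smallest the relabellings can give). At the times with 2 libraries in each arm, the progenitor and fibroblast list was itself lower with camera's preset correlation (adjusted p = 0.0286). Over all libraries it did not pass by the exact test, with a mean log2 difference of -0.06 (exact permutation p = 0.442, adjusted p = 0.510). A smaller stromal share as part of the cause therefore stays open. An effect of the microbiota on matrix and mitochondrial transcripts may remain, as may a difference in adipocyte size or, since the labels do not say whether both arms came from 1 colony, in the origin of the mice, none of which was tested.

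Ide, the insulin-degrading enzyme gene on chromosome 19 at 37268743 to 37337852, chosen after its values were seen, ranged from 121 to 219 CPM in conventional and from 89.0 to 117 CPM in germ-free libraries (log2 fold change -0.77 ± 0.10, adjusted p = 1.30e-04). Across the 12 conventional libraries it varied with Fgfbp3, at 36917550 to 36919615, with r = 0.919 (permutation p = 4e-05, adjusted p = 9.60e-04 over 24 relations), rho = 0.867 (permutation p = 5.70e-04) and r = 0.873 without the 2 farthest libraries; over the 9 germ-free libraries r was 0.447 (exact permutation p = 0.227), rho 0.5 (exact permutation p = 0.178) and r 0.799 without the 2 farthest. The highest r among the other neighbours within 2 Mb, 0.868, was that of Rpl10-ps6, which lies inside Ide, and their median was 0.0288, which argues against variation of the whole neighbourhood. For the 3 genes between Ide and Fgfbp3 the median was -0.148, but r ran from -0.566 to 0.600, highest for Btaf1, so variation of 1 unbroken segment stays open. A candidate explanation is a number of copies of Ide and Fgfbp3 that differs among mice, which DNA of the same mice would have to show, and the fall in germ-free mice is open to a difference in the origin of the mice, while a regulator shared by both genes was not tested.

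Genes of the aryl hydrocarbon receptor pathway, some of whose ligands come from microbes, were looked up after the values were seen. Cyp1a1 fell from 0.918 ± 0.537 to 0.197 ± 0.193 CPM (log2 fold change -2.24 ± 0.53, adjusted p = 0.00542) and Cyp1b1 had -0.35 ± 0.11 (adjusted p = 0.0269), a call lost without the germ-free libraries at ZT02, replicate 2 (0.0507), or ZT22, replicate 2 (0.0545). Ahr had 0.18 ± 0.06 (adjusted p = 0.0313), a call lost without any of 11 single libraries (adjusted p up to 0.118), and Nqo1 (0.165), Tiparp (0.208), Ahrr (0.747) and Cyp1a2 (0.891) did not pass.

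Other genes chosen after their values were seen were Mid1 (-1.26 ± 0.12), Clcn4-2 (-0.60 ± 0.04, adjusted p = 1.11e-07), Dynlt1b (1.18 ± 0.16) and Cd163l1 (-2.02 ± 0.19). Whether these values reflect the microbiota or a difference in the origin of the mice was not tested. The histone gene Hist1h4m (-3.10 ± 0.16) shares reads with near-identical copies and is uncertain. The gene models SLC25A37 and LOXL2, which overlap on chromosome 14, held 241 and 210 counts in conventional and 2 and 15 counts in germ-free libraries, while Slc25a37 had a log2 fold change of -0.18 (adjusted p = 0.139) and Loxl2 -0.42 (adjusted p = 0.0129).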
